A study of Xenopus laevis with 8 samples.

How the data were processed

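Messenger RNA of 8 explant samples was measured by RNA-seq: 2 control and 2 Flag-Pinhead ectoderm explant samples, and 2 control and 2 PhSpMo marginal zone explant samples. Groups and sample numbers were taken from the titles and treatment labels. Per the labels' protocols, mRNA was selected on oligo(dT), fragmented, copied with random hexamers and sequenced on a HiSeq2000. Selection on oligo(dT) leaves out transcripts without a poly(A) tail, and the protocol text states no strand marking, so reads of overlapping antisense genes cannot be told apart. Per the submitters' processing notes, the tools were CASAVA 1.8, HISAT2, SAMtools and HTSeq; the genome build and the counting options are not given in the sources used here. The deposited file holds raw counts per gene for 35649 genes in 16 columns, 2 columns for each sample, with no normalization by the authors. What the 2 columns of a sample are is not stated, and they were added. The names of 2 columns are mistyped and were assigned to control marginal zone sample 1, since each of the other samples has its own 2 columns. Of the genes, 4259 had no count in any column.

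Gene names are those of the file. For LOC identifiers, the NCBI gene number was looked up in a RefSeq gene table of X. laevis v10.1; 21106 of 24441 were found and 10897 were given its symbol. No coordinates are printed, since the build behind the counts is not known.

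Samples of each group were compared before averaging, by the mean over genes with at least 50 counts of a chi-square of their counts. The 2 PhSpMo samples gave 1.43, within the 1.29 to 1.46 found between columns of other samples, while the 2 columns named for a PhSpMo sample differed by 2.38 and 2.44, and columns with the same last digit in the 2 PhSpMo samples by 1.30 and 1.36. The control pairs gave 2.05 in marginal zone and 2.27 in ectoderm, and the Flag-Pinhead pair, with the injected RNA among its counts, 11.9; the median over its expected value was 1.86, 1.98 and 2.92 in these pairs. Summed by that digit, PhSpMo columns differed by 3.41, more than the control pairs, so columns of 2 distinct samples may be crossed. Since the assignment of columns is not known, the PhSpMo columns were summed and counted as 1 unit, which leaves 7 units and 3 residual degrees of freedom; the lone PhSpMo unit is assumed to vary like the other groups. This departs from the fit of 8 libraries fixed before the data were examined; that fit, and another with PhSpMo columns summed by the last digit of their names, are alternatives chosen after seeing the data.

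Differential expression was tested with edgeR 4.0.16 (R 4.3.3): filterByExpr at its default minimum of 10 counts, TMM factors, a design of 1 mean per group over all groups, and quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. This left 22241 genes. Standard errors are the log2 fold change divided by the square root of F. Normalized CPM use TMM-adjusted library sizes; CPM of pnhd per library use total counts. Total counts per sample ran from 12551618 to 19719311, so genes under 1 CPM rest on few counts. TMM factors of the Flag-Pinhead libraries were 0.923 and 0.927. Counting intervals are exact 95% binomial intervals of the ratio of counts between groups. For a group with no count, the floor is 3 counts over the group. Intervals and floors cover counting error only, as PCR copies are not independent molecules.

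The fit was tested on simulated counts drawn with the spread and library sizes of these samples. For each arm all units were given the means of its control group, so the difference between the tissues was not simulated. In the treated group of these counts 200 genes were changed and a further list was raised 1.5-fold, leaving 22021 genes unchanged. After the filter 20459 genes entered the fit for Flag-Pinhead RNA and 20549 that for PhSpMo. The lone PhSpMo unit was drawn with the spread of the other groups, so its assumed spread was not checked. For Flag-Pinhead RNA it recovered 74.6% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold. For PhSpMo the shares were 61.2%, 89.6% and 98.5%. Of the calls 6.0% and 5.3% were false.

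Before the data were examined, 23 gene lists and the rule for naming genes were fixed. Named genes are pnhd, the 10 rising and 10 falling genes with the largest log2 fold change that have an adjusted p under 0.05, an average log2 CPM of at least 1, a symbol and both samples of a group on the same side (of 2 qualifying homeologs, the one with the larger change), and from each list up to 4 members with the lowest p (up to 2, as values, where none passed). All of the genes with the largest changes are given in the text, and of the list members it gives a part, chosen from those the rule names; a single item withheld for evaluation is not reported here. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, adjusted over lists, with an estimated correlation and fry beside it. The lists are early mesoderm, ventrolateral and posterior mesoderm, paraxial and myogenic mesoderm, dorsal organizer, Nodal and activin targets, FGF and MAPK feedback and immediate early genes, FGF ligands and receptors, BMP targets, Wnt/beta-catenin targets, Hox genes, endoderm, epidermis, multiciliated cells and ionocytes, neural plate, germ plasm, blood and endothelial precursors, p53 response, innate immune response, heat shock and unfolded protein stress, cell cycle, gastrulation movements and adhesion, retinoic acid pathway, and ribosomal proteins. They share members: vegt, for example, is in the early mesoderm and endoderm lists, and gata2 in the ventrolateral, BMP and epidermis lists.

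Overlaps of calls were tested with one-sided Fisher's exact tests over all genes tested, adjusted over 4 direction pairs. Members of lists were set against all other tested genes with Wilcoxon's rank-sum test for the effect of scaling. For comparisons that share controls, 20 sets of unchanged groups were simulated on those controls. Alternatives were DESeq2 1.42.0, DESeq2 size factors and upper-quartile scaling in edgeR, other filters, a robust spread estimate, fits of only the groups compared, the replicate number as a block, summed L and S counts, stricter thresholds and leaving out each sample. No group has 3 samples or more, so other splits of the samples and tests for outlying samples were not made.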

Results

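RNA was sequenced from explants of Xenopus laevis gastrulae to ask what gain and loss of Pinhead, a secreted signalling protein encoded by pnhd, do to gene expression. In the gain-of-function arm, ectoderm explants (animal caps, tissue that forms epidermis when left alone) expressed Flag-Pinhead, an epitope-tagged Pinhead, from 1.5 ng of injected RNA and were compared with untreated ectoderm explants, all labelled stage 11. In the loss-of-function arm, marginal zone explants (the equatorial belt that forms mesoderm) carried PhSpMo, the MO oligonucleotide used to deplete Pinhead, at 40 ng per blastomere from the 4-cell stage. They were compared with untreated marginal zone explants. The sample labels give stage 10.5 for the marginal zone and the series text gives stage 11. Each of the 4 groups has 2 samples. Total counts were 19719311 and 17534756 for control ectoderm, 15569096 and 15227252 for Flag-Pinhead ectoderm, 12551618 and 14971466 for control marginal zone, and 14239916 and 14415419 for PhSpMo marginal zone. The 2 PhSpMo samples differed by no more than the 2 columns of a single sample do (mean chi-square 1.43 per gene, against 2.05 between the control marginal zone samples and 1.29 to 1.46 between columns of the other samples). The 2 columns named for each PhSpMo sample differed more (2.38 and 2.44), and summed by the last digit of their names they differed by 3.41, so columns of 2 distinct samples may have been crossed. With the assignment unknown, PhSpMo was counted as 1 sample, so PhSpMo values carry no SD and the group is assumed to vary like the other 3. Controls are labelled as untreated, so an effect of injection itself cannot be separated from either treatment. Nothing states that the samples of a group came from separate clutches, so p-values measure the spread between these samples, which may be technical.

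Counts of the targeted gene followed the labels in every library. They measure RNA and not Pinhead protein, so their fall with PhSpMo does not measure depletion. Early mesoderm genes fell in the same arm, with a list median of -0.78 on the log2 scale. The medians of the endoderm and epidermis lists were -0.85 and -0.62. Of 23 lists 17 passed camera's test downwards there and 1 upwards, so the fall of mesoderm genes does not measure depletion either. X. laevis is allotetraploid and carries a long (L) and a short (S) copy of most genes. In Flag-Pinhead ectoderm, pnhd.L took 31777 and 59876 CPM (counts scaled to each library's total), 3.18% and 5.99% of all counts with pnhd.S, against 16.1 and 18.3 CPM in control ectoderm. These counts include the injected RNA. In marginal zone explants pnhd.L stood at 93.7 and 89.2 CPM in the controls and at 58.9 and 55.0 CPM with PhSpMo, and pnhd.S (LOC108706889 in the deposited table) at 79.8 and 83.6 against 34.1 and 38.4 CPM. With PhSpMo, normalized pnhd.S fell from 79.1 ± 2.36 to 33.3 CPM (adjusted p = 1.02e-08, edgeR's quasi-likelihood test) and pnhd.L had a log2 fold change of -0.76 (SE 0.20, adjusted p = 0.0079). The call of pnhd.L ended with DESeq2 (adjusted p = 0.339), with edgeR's robust spread estimate (0.472) and without control marginal zone replicate 1 (0.0937) or 2 (0.0707). In these fits the spread of pnhd.L is shared with the Flag-Pinhead libraries. A fit of the marginal zone libraries alone gave a log2 fold change of -0.75. With PhSpMo as 1 unit it measures no spread within that group, so it does not settle the call. In ectoderm, pnhd.S rose with Flag-Pinhead RNA from 1.24 ± 0.26 to 13.5 ± 2.87 normalized CPM (SD, n = 2 each), a log2 fold change of 3.45 (SE 0.20, adjusted p = 2.12e-13).

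**Figure D1:**
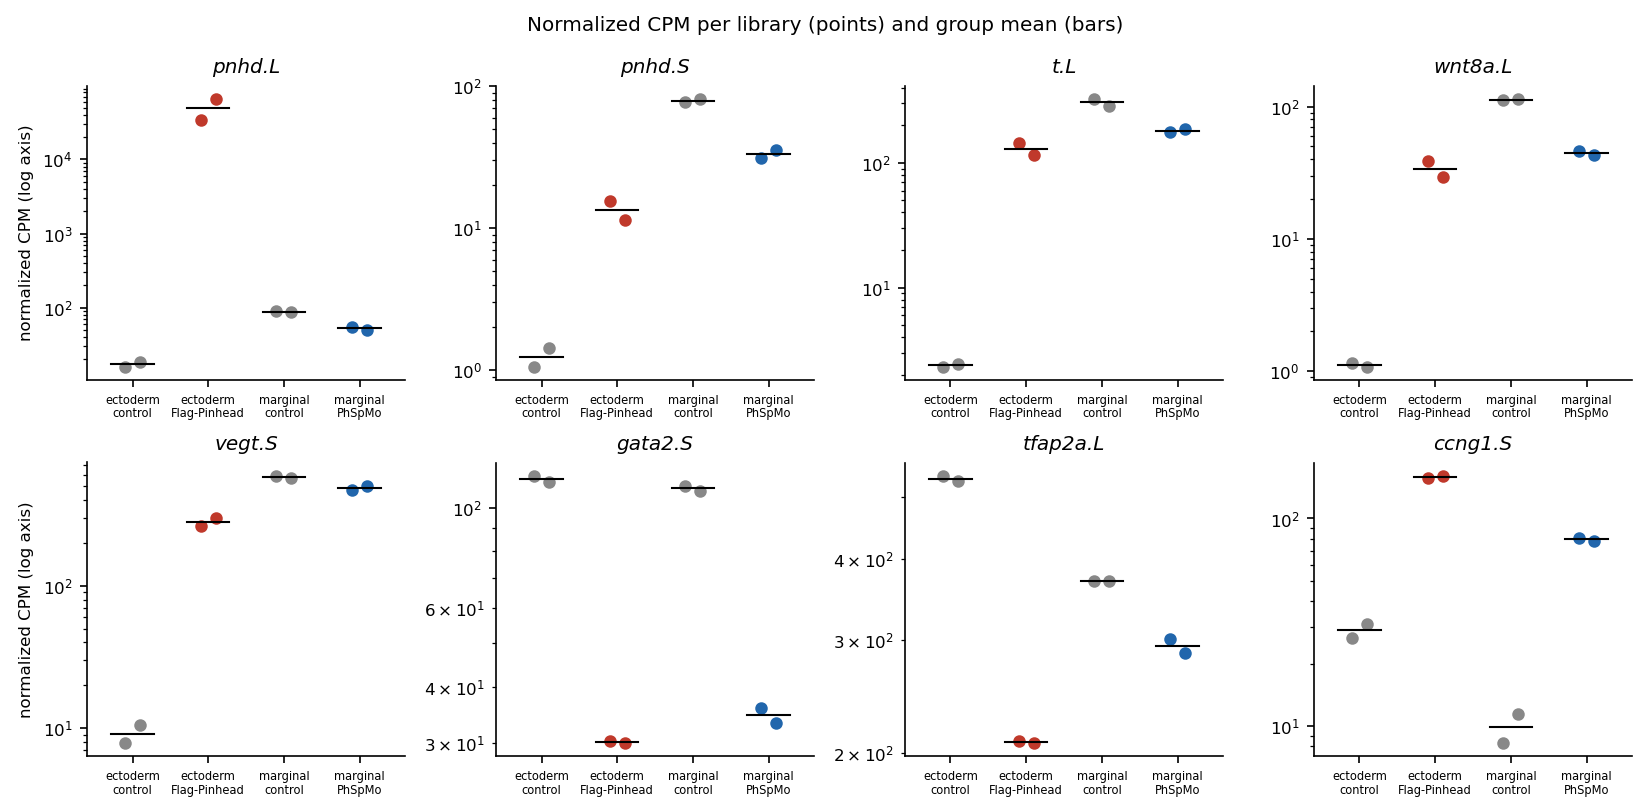
Normalized CPM on log axes for 8 genes, 1 panel each, in the 4 groups; points are the 2 samples of a group as named in the labels and bars their means. For t.L the control ectoderm samples average 2.39 and the Flag-Pinhead samples 130 CPM, and for ccng1.S both treated groups lie above their controls.

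The comparison of control marginal zone with control ectoderm checks the tissue labels and gives the baseline for both arms. Mesoderm and endoderm genes were far higher in the marginal zone. All 20 tested genes of the Nodal and activin target list, all 20 of the endoderm list and 27 of 28 early mesoderm genes were higher there (20, 20 and 28 adjusted over the list alone), with no member lower. The T-box regulators vegt.L and eomes.S reached 618 ± 8.42 and 207 ± 5.6 CPM in the marginal zone against 13.3 ± 0.609 and 1.36 ± 0.495 in ectoderm (SD, n = 2 each). The endoderm regulator mixer.S stood at 267 ± 3.42 against 0.165 ± 0.0898 CPM. Of the genes with the largest differences among those with a symbol and an average log2 CPM of at least 1, bix4.L and bix2.L (Mix-family homeobox genes) had no count in control ectoderm and were at least 1090-fold and 878-fold higher in the marginal zone, taking 3 counts over the group as the floor. Likewise cml, xenf, bix1.1.S, cer1.S, sebox.L and nodal2.L were at least 371, 317, 302, 265, 229 and 183-fold higher, and mix1.S and t.S, with 2 and 1 ectoderm counts, had ratios of 4120 (counting interval 1140 to 34000) and 3400 (609 to 134000).

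Epidermal genes went the other way. Of 30 tested members of the epidermis list 19 were lower and 7 higher in the marginal zone (19 and 8 adjusted over the list alone), among them the keratin krt12.L at 33.7 ± 0.131 against 236 ± 27.8 CPM and the epidermal regulator grhl3.S at 136 ± 2.34 against 292 ± 8.88 CPM. The list passed camera's test with a preset correlation (adjusted p = 1.16e-06), and its adjusted p was 0.204 with an estimated correlation. Ribosomal protein genes were lower for 100 of 116 members and higher for 2 (101 and 2 adjusted over the list alone; camera adjusted p = 2.92e-13, and adjusted p = 0.211 with an estimated correlation). Several genes with no assigned list were read in ectoderm and had no count in the control marginal zone, led by ephx4.S, XB22063249.S, neto1.L, ptchd1.S, post3.S, cpo.L and glb1l2.S, at least 316, 229, 121, 108, 91.1, 41.4 and 35.3-fold lower there. The genes ankrd13b.S, tmem132e.S and dnah1.L, with 2, 3 and 2 marginal zone counts, had ratios of 290 (79.9 to 2400), 233 (79.4 to 1130) and 213 (58.7 to 1760). In all, 11737 of 22241 genes differed (5889 higher and 5848 lower in the marginal zone). Tissue, stage label and the 2 experiments cannot be told apart in this comparison. Of 23 lists 18 passed camera's test, 15 higher and 3 lower in the marginal zone, and with an estimated correlation 5 did: early mesoderm, endoderm, Nodal and activin targets, paraxial and myogenic mesoderm, and gastrulation movements.

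Flag-Pinhead RNA switched on mesoderm genes in ectoderm explants. Of 28 tested early mesoderm genes 24 rose and none fell (25 adjusted over the list alone; camera adjusted p = 3.28e-84). The T-box regulator t.L (Brachyury) went from 2.39 ± 0.0904 to 130 ± 19.4 CPM (SD, n = 2 each), a log2 fold change of 5.76 (SE 0.13). The maternal and zygotic T-box gene vegt rose in both copies, vegt.S from 9.19 ± 1.85 to 280 ± 27.3 CPM. The ligand gene wnt11b.L, whose product drives convergent extension, rose from 10.8 ± 0.856 to 348 ± 94 CPM. The ligand genes wnt8a.L and fgf8.L changed by 4.91 (SE 0.17) and 6.59 (SE 0.21) on the log2 scale. In comparison, control marginal zone held vegt.S at 580 ± 12.6 and wnt8a.L at 112 ± 1.56 CPM, above the 34.0 ± 6.69 CPM of wnt8a.L in Flag-Pinhead ectoderm. Nodal and activin targets rose for 10 of 20 members and fell for none (12 and 0 adjusted over the list alone; camera adjusted p = 1.02e-11). They included the TGF-beta ligand gdf3.S and mixer.S, with log2 fold changes of 5.33 (SE 0.18) and 5.95 (SE 0.28), and eomes.S at 3.22 (SE 0.22). Endoderm genes rose for 7 of 20 members (7 adjusted over the list alone, camera adjusted p = 1.53e-14). They included sox17b.2.L, from 0.869 ± 0.342 to 5.6 ± 1.81 CPM. Both copies of vegt and mixer.S, counted above in the other lists, were also among the 7, so these lists are not separate evidence.

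Genes downstream of FGF and MAPK signalling rose with the RNA for 29 of 33 members, and none fell (30 and 0 adjusted over the list alone; camera adjusted p = 2.29e-44). The Ras-like GTPase gene rasl11b.L rose from 6.81 ± 1.34 to 158 ± 13.7 CPM, the feedback inhibitor spry1.L from 4.36 ± 0.688 to 37.4 ± 6.15 CPM, and the immediate early gene egr1.L from 18.2 ± 2.31 to 75.0 ± 8.16 CPM. Among FGF ligands and receptors 9 of 17 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 8.8e-10); the 2 that fell were both copies of the receptor fgfr4, fgfr4.L at -1.77 (SE 0.07) and fgfr4.S at -1.55 (SE 0.06) on the log2 scale. Wnt/beta-catenin targets rose for 16 of 28 members and 1, nkd1.S, fell (17 and 1 adjusted over the list alone; camera adjusted p = 2.81e-14). Their rise included the posterior homeobox genes cdx1.S, cdx2.S and cdx4.L, at 4.69 (SE 0.23), 4.29 (SE 0.18) and 3.88 (SE 0.19). Of 7 tested Hox genes 5 rose (6 adjusted over the list alone; camera adjusted p = 4.76e-06), with hoxd1.S going from 0.108 ± 0.00919 to 10.4 ± 1.22 CPM.

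Paraxial and myogenic mesoderm genes rose for 11 of 18 members (12 adjusted over the list alone; camera adjusted p = 6.73e-08). They included both copies of the Notch ligand dll1 at 3.01 (SE 0.11) and 2.18 (SE 0.13). Dorsal organizer genes rose for 13 of 25 members and fell for none (13 and 0 adjusted over the list alone; camera adjusted p = 4.03e-10, and adjusted p = 0.0767 with an estimated correlation), including the notochord homeobox genes not.S and not.L at 2.84 (SE 0.12) and 2.73 (SE 0.16). In the neural plate list 27 of 48 members rose and 6 fell (27 and 7 adjusted over the list alone; camera adjusted p = 1.18e-13). The lowest p were those of the forkhead genes foxd4l1.1.S and foxd4l1.1.L, at 3.86 (SE 0.13) and 5.27 (SE 0.20). Genes of gastrulation movements and adhesion rose for 18 of 38 members and fell for 4 (19 and 5 adjusted over the list alone; camera adjusted p = 6.72e-10). The planar polarity gene prickle1.S stood at 205 ± 15.7 against 27.4 ± 4.77 CPM. Ventrolateral and posterior mesoderm genes moved both ways: 22 of 37 rose and 9 fell (23 and 10 adjusted over the list alone; camera adjusted p = 4.49e-06, and adjusted p = 0.341 with an estimated correlation). Those that fell were both copies of gata2, 2 copies of szl, bambi.L, ventx2.1.S, bmp4.S, msx1.S and bmp7.2.L, which were also in the BMP list.

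Most epidermal genes and BMP targets past the test fell. In the epidermis list 17 of 30 members fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p = 7.09e-13, and adjusted p = 0.0767 with an estimated correlation). The ectodermal regulators tfap2a.L and gata2.S dropped from 534 ± 7.53 to 208 ± 1.05 CPM and from 116 ± 2.75 to 30.1 ± 0.181 CPM. The 4 that rose were itln1.L, tp63.L, upk3b.L and grhl2.L. Of 35 BMP targets 16 fell and 9 rose (17 and 10 adjusted over the list alone; camera adjusted p = 5.98e-05, and adjusted p = 0.341 with an estimated correlation and 0.0532 with fry). The largest drop was that of szl.L, a secreted BMP feedback inhibitor, at -2.68 on the log2 scale (SE 0.19); reads of szl.L and its near-copy szl may be shared. The list of multiciliated cells and ionocytes did not pass (9 of 20 rose and 6 fell, also adjusted over the list alone; camera adjusted p = 0.0762). Its members parted: foxj1.S, a regulator of motile cilia, rose from 6.27 ± 0.00537 to 52.0 ± 13.0 CPM while foxi4.2.S, an ectodermal forkhead gene, fell from 198 ± 5.32 to 31.5 ± 3.56 CPM. The 2 copies of foxi1 moved apart, foxi1.L by 1.50 and foxi1.S by -1.51.

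Stress and growth genes moved too. In the p53 response list 15 of 25 members rose and 1, ddb2.L, fell (16 and 3 adjusted over the list alone; camera adjusted p = 1.78e-24). The ubiquitin ligase mdm2.L and cyclin ccng1.S, both p53 targets, rose from 41.0 ± 1.27 to 159 ± 11.8 and from 28.9 ± 3.15 to 158 ± 2.67 CPM. Heat shock and unfolded protein genes rose for 10 of 20 members and fell for 2 (11 and 2 adjusted over the list alone; camera adjusted p = 7.88e-05, and adjusted p = 0.0767 with an estimated correlation). The endoplasmic reticulum chaperone hspa5.L went from 104 ± 3.9 to 558 ± 17.2 CPM. Ribosomal protein genes rose for 64 of 116 members (80 rose and 1 fell adjusted over the list alone). The list's camera adjusted p was 9.78e-06, and 0.396 with an estimated correlation. Its median log2 fold change was 0.25, with 0.52 (SE 0.07) for rps23.L and 1.11 (SE 0.07) for rps9. Of 34 cell cycle genes 13 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 0.000779, and adjusted p = 0.0767 with an estimated correlation), ccna2.L from 634 ± 19.7 to 455 ± 3.94 CPM. The retinoic acid, innate immune, germ plasm and blood lists did not pass (camera adjusted p = 0.076, 0.994, 0.426 and 0.452). Their called members numbered 5 risen and 2 fallen of 13, 3 and 1 of 16, 0 and 1 of 12, and 1 and 0 of 5; adjusted over the list alone, these were the same numbers except for germ plasm, with 0.

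Among genes with a symbol and an average log2 CPM of at least 1, the largest rises were those of pnhd.L and of bix4.L, cml and sebox.L, which had no count in control ectoderm and were at least 42.4, 33.7 and 26.7-fold higher with the RNA. The genes t.S, wnt8a.S, foxa4.L, hes5.9.L and zg16.S, with 1 to 3 control counts, had ratios of 334 (counting interval 59.5 to 13300), 180 (49.3 to 1490), 206 (70.0 to 1000), 218 (38.5 to 8650) and 174 (47.8 to 1450), and flrt3.L, an adhesion protein gene, changed by 7.36 (SE 0.23). The largest falls were smaller: log2 fold changes of -3.64 for nedd9.L, -3.1 for the cyclin E gene ccne2.S, -2.75 for apold1.L, -2.68 for szl.L, -2.66 for foxi4.2.S, -2.57 for xepsin.L, -2.52 for olig3.S, -2.42 for rgcc.L and -2.28 for both rgs2.L and s1pr5.L. In all, 6088 of 22241 genes changed (3441 rose and 2647 fell; edgeR, adjusted p under 0.05), 1609 rising and 195 falling at least 2-fold. DESeq2 called 3745 genes, and leaving out control ectoderm replicate 1 or 2 left 4054 or 4069 calls, 1690 or 1639 of them falls. Of 23 lists 18 passed camera's test, and 11 with an estimated correlation: those given above without such a p, that is early mesoderm, paraxial mesoderm, Nodal and activin targets, both FGF lists, Wnt targets, Hox genes, endoderm, neural plate, p53 response and gastrulation movements.

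PhSpMo lowered mesoderm and endoderm genes in marginal zone explants. Of 28 early mesoderm genes 17 fell and none rose (18 and 0 adjusted over the list alone; camera adjusted p = 1.09e-15). The forkhead genes foxc1.L and foxc2.L went from 61.4 ± 3.37 to 11.8 CPM and from 15.5 ± 0.319 to 2.66 CPM (SD, n = 2 for controls; PhSpMo is 1 sample), and wnt8a.L from 112 ± 1.56 to 44.8 CPM, a log2 fold change of -1.33 (SE 0.10, adjusted p = 6.03e-10). Endoderm genes fell for 16 of 20 members (18 adjusted over the list alone; camera adjusted p = 2.67e-18). Among them were gata6.S and gata4.S at 16.7 against 44.0 ± 3.27 and 9.53 against 27.5 ± 0.333 CPM, and the secreted antagonist cer1.S at 4.85 against 21.0 ± 4.54 CPM. The call of gata6.L (log2 fold change -1.65, SE 0.17) ended with DESeq2 (adjusted p = 0.481).

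Posterior and ventrolateral genes fell as well. In the ventrolateral and posterior mesoderm list 27 of 37 members fell and 1, ventx2.1.L, rose (28 and 1 adjusted over the list alone; camera adjusted p = 1.65e-31, and adjusted p = 0.0841 with an estimated correlation). Both copies of hoxd1 fell, hoxd1.S from 5.64 ± 0.326 to 0.481 CPM and hoxd1.L from 6.33 ± 0.458 to 0.642 CPM, and cdx4.S and cdx2.S had log2 fold changes of -2.16 (SE 0.20) and -2.24 (SE 0.23). Hox genes fell for 3 of 7 members (3 adjusted over the list alone; camera adjusted p = 0.000283, and adjusted p = 0.0711 with an estimated correlation). Wnt/beta-catenin targets fell for 12 of 28 members and none rose (15 and 1 adjusted over the list alone; camera adjusted p = 3.16e-10, and adjusted p = 0.0605 with an estimated correlation). Of 35 BMP targets 25 fell and 1 rose (26 and 1 adjusted over the list alone; camera adjusted p = 1.43e-24, and adjusted p = 0.0841 with an estimated correlation). They included gata2.S, from 110 ± 2.19 to 34.6 CPM, and msx2.L, from 37.3 ± 0.175 to 8.82 CPM. Paraxial and myogenic genes fell for 8 of 18 members (9 adjusted over the list alone; camera adjusted p = 8.48e-06, and adjusted p = 0.0605 with an estimated correlation). The protocadherin pcdh8.2.L fell from 120 ± 7.32 to 50.2 CPM. Dorsal organizer genes fell for 9 of 25 members (13 adjusted over the list alone; camera adjusted p = 5.47e-06, and adjusted p = 0.15 with an estimated correlation), such as the Wnt antagonist frzb.S, from 59.7 ± 2.99 to 22.7 CPM.

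FGF and MAPK genes fell for 17 of 33 members and rose for 2, rasl11b.L and dusp4.L (18 and 3 adjusted over the list alone; camera adjusted p = 2.37e-07, and adjusted p = 0.0841 with an estimated correlation). The immediate early genes fos.L and junb.L fell, at -1.9 (SE 0.12) and -1.36 (SE 0.09), while rasl11b.L rose by 1.05 (SE 0.09). Nodal and activin targets fell for 6 of 20 members (8 adjusted over the list alone; camera adjusted p = 0.0117, and adjusted p = 0.131 with an estimated correlation), with log2 fold changes of -1.05 (SE 0.21) for nodal2.L, -0.51 (SE 0.07) for mixer.S, -0.77 (SE 0.16) for lefty.S and -0.4 (SE 0.10) for gdf3.S, whose call ended with DESeq2 (adjusted p = 0.0545). FGF ligands and receptors did not move as a list (3 of 17 rose and 6 fell, also adjusted over the list alone; camera adjusted p = 0.891). Retinoic acid genes fell for 9 of 13 members and rose for 2 (9 and 2 adjusted over the list alone; camera adjusted p = 7.12e-06, and adjusted p = 0.0605 with an estimated correlation), and genes of gastrulation movements for 20 of 38 with 3 rising (21 and 3 adjusted over the list alone; camera adjusted p = 2.37e-07, and adjusted p = 0.051 with an estimated correlation).

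Ectodermal genes also fell. In the epidermis list 19 of 30 members fell and none rose (21 and 0 adjusted over the list alone; camera adjusted p = 4.96e-25, and adjusted p = 0.0605 with an estimated correlation). The keratin krt5.7.L went from 262 ± 4.08 to 120 CPM and upk3b.L from 39.3 ± 3.3 to 12.1 CPM. In the neural plate list 22 of 48 fell and 1, gmnn.L, rose (24 and 2 adjusted over the list alone; camera adjusted p = 1.09e-08, and adjusted p = 0.0711 with an estimated correlation), with foxd4l1.1.S at 8.15 against 21.2 ± 1.93 CPM. The list of multiciliated cells and ionocytes did not pass (5 of 20 rose and 3 fell, also adjusted over the list alone; camera adjusted p = 0.197), though foxi1.L rose from 13.9 ± 1.42 to 59.6 CPM. Ribosomal protein genes fell for 40 of 116 members (52 adjusted over the list alone; camera adjusted p = 7.34e-09, and adjusted p = 0.301 with an estimated correlation). Heat shock and unfolded protein genes fell for 5 of 20 and rose for 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00539, and adjusted p = 0.141 with an estimated correlation). Innate immune genes fell for 5 of 16 members (5 adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.131 with an estimated correlation), although the list's median log2 change was 0.03 and its mean -0.61. The cytokine signalling inhibitor socs3.L went from 9.13 ± 0.877 to 0.481 CPM and irf1.L from 2.02 ± 0.34 to 0.257 CPM. Cell cycle, germ plasm and blood lists did not pass (camera adjusted p = 0.891, 0.302 and 0.507), with 9 risen and 10 fallen of 34, 1 and 1 of 12, and 1 and 0 of 5, also adjusted over the list alone.

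The p53 response list was the only 1 of the 23 to pass camera's test upwards with PhSpMo (adjusted p = 5.62e-26). With fry, blood and endothelial precursors passed upwards as well (adjusted p = 0.038). Of the 25 p53 response members 12 rose and 3 fell (12 and 4 adjusted over the list alone). The rise of ccng1.S was from 9.85 ± 2.23 to 79.5 CPM and that of eda2r.L from 13.1 ± 1.06 to 102 CPM. That of mdm2.L was from 26.8 ± 2.2 to 130 CPM and that of the kinase plk2.L from 18.3 ± 1.48 to 91.3 CPM. The 3 that fell were btg2.S, plk3.L and sesn2.L.

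Among genes chosen by the same rule with PhSpMo, the largest rises included tnfrsf6b.L, a decoy receptor, at 4.21 (SE 0.33), zg16.S at 4.16 (SE 0.48), the complement receptor c3ar1.L at 3.83 (SE 0.10), slc26a9.S at 3.65 (SE 0.19), nppb.S at 3.58 (SE 0.45), trnal-aag at 3.55 (SE 0.44), col17a1.L at 3.38 (SE 0.26), sctr.L at 3.35 (SE 0.54) and nt5c3a.L at 3.33 (SE 0.23). The other, chrng.L, had 8 counts with PhSpMo and none in controls, at least 2.43-fold higher. Besides socs3.L and hoxd1.S, XB22063314.S and krt.S fell, at -3.48 (SE 0.24) and -3.22 (SE 0.55). The genes krt12.5.L, fucolectin.S and slc26a4l.L had no count with PhSpMo and were at least 3.29, 2.92 and 2.56-fold lower. With 1, 2 and 1 counts under PhSpMo, otog.L, atp6v0d2.L and adgrf1.L had ratios of 15.3 (counting interval 2.34 to 649), 11.0 (2.66 to 96.7) and 11.0 (1.56 to 476). The calls of chrng.L, krt12.5.L, fucolectin.S, slc26a4l.L, otog.L, adgrf1.L and trnal-aag ended with DESeq2 (adjusted p = 0.0614, 0.0582, 0.0691, 0.0902, 0.0672, 0.17 and 0.13), and that of atp6v0d2.L without control marginal zone replicate 2 (0.196). In all, 4153 of 22241 genes changed (1828 rose and 2325 fell), 329 rising and 504 falling at least 2-fold. DESeq2 called 2266 genes, and leaving out control marginal zone replicate 1 or 2 left 2672 or 2471 calls, 1100 or 998 of them rises. Of 23 lists 18 passed camera's test and 3 with an estimated correlation: early mesoderm, endoderm and p53 response (each at adjusted p = 0.0428).

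**Figure D2:**
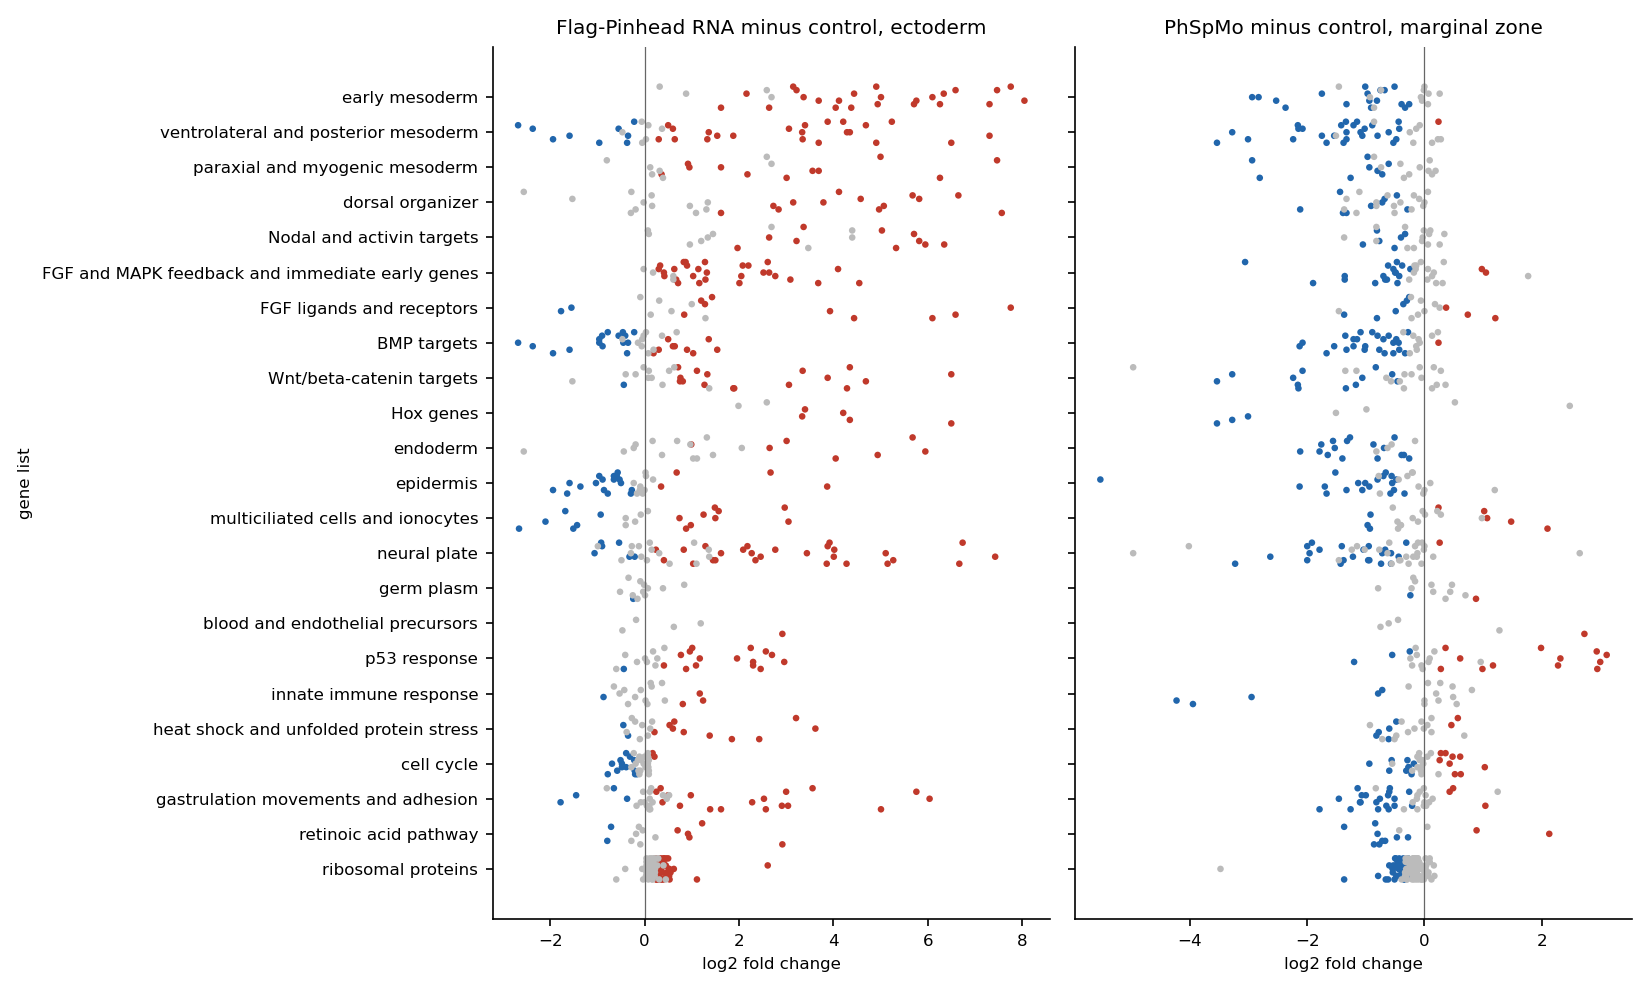
Log2 fold change of each tested member of the 23 gene lists, Flag-Pinhead RNA minus control in ectoderm (left) and PhSpMo minus control in marginal zone (right); red members rose and blue members fell at an adjusted p under 0.05, grey did not pass. Of 28 early mesoderm members 24 are red on the left and 17 blue on the right, while p53 response members are red on both sides (15 and 12 of 25).

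Setting the arms side by side asks whether genes raised by gain of Pinhead are lowered by its loss. Of the 28 early mesoderm genes 24 rose with Flag-Pinhead RNA, 17 fell with PhSpMo and 15 did both. None fell with the RNA or rose with PhSpMo, so no other combination could occur. The same opposite change was found for 17 of 33 FGF and MAPK genes, 11 of 28 Wnt targets, 14 of 48 neural plate genes and 8 of 25 organizer genes. It was also found for 6 of 20 endoderm genes and 3 of 20 Nodal and activin targets. Epidermal genes mostly fell in both arms (16 of 30), and BMP targets were split, with 11 of 35 falling in both, gata2.S among them, and 8 rising with the RNA and falling with PhSpMo. Of the p53 response genes 10 of 25 rose in both. Except for the p53 list, tested below, these counts were not set against the number of members that moved in each arm. They therefore show lists that moved in both arms, and not that the same members did so more than independent calls would. Over all genes, 783 rose with the RNA and fell with PhSpMo, 2.18 times the 359.7 of independent lists (one-sided Fisher's exact test, adjusted p = 2.79e-119), and 374 fell and rose (217.6 for independent lists, adjusted p = 6.39e-28). Shared calls in the same direction were also in excess, 474 risen in both (282.8 for independent lists, adjusted p = 1.92e-33) and 403 fallen in both (276.7, adjusted p = 2.55e-16). DESeq2 gave 474 and 118 opposite changes in these directions, and 262 and 236 alike. The 374 became 212 or 200 without control ectoderm replicate 1 or 2 and 196 or 172 without control marginal zone replicate 1 or 2, and the 403 became 264 without the last of these. Among genes changed at least 2-fold in each arm, 210 rose in both (23.8 for independent lists), 144 rose and fell (36.5), 19 fell in both (4.4) and 3 fell and rose (2.9). Across all genes, which are not independent replicates, fold changes of the 2 arms had Pearson's r of 0.135 and Spearman's rho of -0.063. Of the 3441 genes that rose with the RNA, 55.4% had a negative log2 fold change with PhSpMo, with a median of -0.07. Of the 2647 that fell with the RNA, 46.6% did, with a median of 0.02. All 4 direction pairs were in excess, so the 783 alone do not show a mirrored response. These arms share no library, but the calls of all comparisons come from 1 fit with 1 spread per gene. A gene with a low spread or many counts passes more easily in each of them, which independent lists do not allow for.

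**Figure D3:**
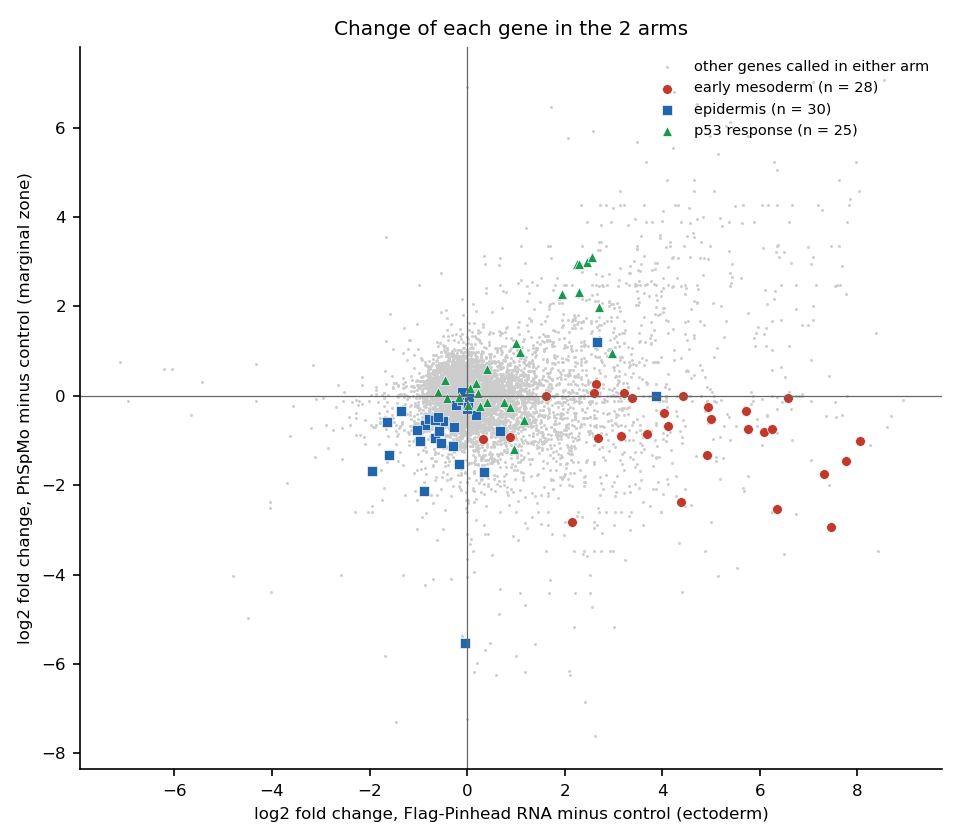
Log2 fold change with Flag-Pinhead RNA in ectoderm (horizontal) against that with PhSpMo in marginal zone (vertical), 1 point per gene; grey points are other genes called in either arm, and pnhd.L is left out. Early mesoderm members lie mostly at the lower right (15 of 28 called so), epidermis members at the lower left (16 of 30) and p53 response members at the upper right (10 of 25).

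Each arm shares its control libraries with the tissue comparison. Of genes changed by Flag-Pinhead RNA, 1058 rose and were higher in the marginal zone (911.1 for independent lists, adjusted p = 1.24e-09), 1024 rose and were lower there (904.8, 4.96e-07), 1032 fell and were higher (700.9, 1.66e-50) and 711 fell and were lower (696, 0.247). Without control ectoderm replicate 1 or 2 the last 3 counts were 544 or 595, 605 or 613, and 404 or 366. The covariance of fold changes was 0.300, against 0.0839 when unchanged groups were simulated on the same control ectoderm libraries, and Pearson's r was 0.207 against a simulated 0.44. Of genes changed by PhSpMo, 778 fell and were higher in the marginal zone than in ectoderm (615.6 for independent lists, adjusted p = 2.35e-15), 935 fell and were lower there (611.3, 1.01e-53), 716 rose and were higher (484, 5.14e-35) and 369 rose and were lower (480.7, 1). Without control marginal zone replicate 1 or 2 these 4 were 514 or 517, 597 or 508, 354 or 306, and 208 or 206. That covariance was -0.180 against a simulated -0.108, and r was -0.166 against -0.523. At 2-fold or more the balance turned, with 225 opposite and 496 alike for the RNA and 260 and 146 for PhSpMo. By the signs of the simulated covariances, shared controls push the RNA arm to change like the tissue comparison and PhSpMo to change opposite to it. The controls are 2 libraries per tissue and could not be split, so part of an excess on those sides may come from them. This includes the larger counts at 2-fold or more. The excesses of 1024 and 1032 with the RNA and of 935 and 716 with PhSpMo run against that push. For these, the values argue against the shared controls.

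The L and S copies of a gene moved alike more often than not. Of pairs with a call in either copy, 1423 of 1936 (73.5%) had the same sign with the RNA and 1155 of 1489 (77.6%) with PhSpMo. Over 4143 pairs with both copies tested, fold changes correlated with Pearson's r of 0.483 and Spearman's rho of 0.378 for Flag-Pinhead RNA, and 0.349 and 0.398 for PhSpMo. Of the pairs with both copies called, 594 of 663 (89.6%) and 402 of 442 (91.0%) went the same way. Among the exceptions, chosen after their values were seen, were foxi1 with the RNA and rasl11b with PhSpMo (rasl11b.L at 1.05 and rasl11b.S at -0.46). Reads that fit both copies could be shared between them, so values of single copies are uncertain to that extent.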

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

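Most named genes and fewer gene lists kept their direction and call. Named genes kept both under every alternative for 90 of 92 genes with Flag-Pinhead RNA, 78 of 93 with PhSpMo and 101 of 102 between the tissues, and gene lists for 12, 5 and 7 of 23. No named gene reversed. DESeq2 size factors and upper-quartile scaling changed no call of a named gene or list. Where the cause of a change is not given below, the cause was not tested.

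DESeq2 called 3745 genes for Flag-Pinhead RNA and 2266 for PhSpMo, 592 opposite and 498 alike between the arms, 1160 opposite and 1038 alike between the RNA arm and the tissues, and 588 and 897 for PhSpMo and the tissues. With it pnhd.L stood at -0.77 (adjusted p = 0.339) with PhSpMo, and 16 of 287 named-gene calls ended. The robust spread estimate gave -0.76 for pnhd.L with PhSpMo (adjusted p = 0.472).

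Stricter thresholds leave fewer genes by construction. At an adjusted p under 0.01, PhSpMo changed 2658 genes, the arms shared 685 opposite and 568 alike, and the tissue calls shared 1289 and 1150 with the RNA arm and 698 and 967 with PhSpMo. At 2-fold or more, 1804, 833 and 3709 genes changed with the RNA, with PhSpMo and between the tissues; the arms shared 147 opposite and 229 alike, so the larger count changed sides, and the tissue calls shared 225 and 496 with the RNA arm and 260 and 146 with PhSpMo, which changed sides too. Without a filter on low counts 18, 16 and 14 lists passed, and with fry 19, 19 and 21, where BMP targets lost their call with the RNA (adjusted p = 0.0532). The calls lost without the filter were Hox genes (0.109) and innate immune response (0.189) for PhSpMo, and FGF ligands and receptors (0.771), Hox genes (0.0742), heat shock and unfolded protein stress (0.136) and retinoic acid pathway (0.167) between the tissues. With only the libraries of the 2 groups compared, FGF ligands and receptors (0.091) and germ plasm (0.0674) lost theirs between the tissues. An estimated correlation left 11, 3 and 5 of the 18 lists past camera's test in each comparison.

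Lists that reversed had not passed the test in the report. Without a filter on low counts these were multiciliated cells and ionocytes (adjusted p = 0.759) and innate immune response (0.993) for the RNA, FGF ligands and receptors (0.556) for PhSpMo, and blood and endothelial precursors (0.871) between the tissues. With only the libraries of the 2 groups compared, FGF ligands and receptors (0.998) and cell cycle (0.557) reversed for PhSpMo, and with the replicate block cell cycle did (0.975).

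The replicate block took the 8 libraries as named and the replicate number as a factor within the fit. It gave 6180, 5372 and 11875 changed genes and 19, 18 and 18 lists. In ectoderm, replicates of the same number did not deviate together (correlation -0.05 over 13085 genes), so they share only a number. In marginal zone the correlation was -0.022, which decides nothing, since the PhSpMo samples as named differ only like columns of a single sample. The 2 alternatives chosen after seeing the data gave 6518, 5662 and 12070 changed genes with PhSpMo samples as 2 libraries, and 5860, 5058 and 11555 with PhSpMo columns regrouped by last digit, the assignment if columns were crossed.

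Leaving out 1 sample leaves fewer samples, and a lone sample is assumed to vary like the other groups. Changed genes ranged from 4054 to 6107 for the RNA and from 2471 to 3717 for PhSpMo, pnhd.L with PhSpMo from -0.81 to -0.72, and homeologs called alike from 88.7% to 92.7% and from 91.4% to 94.3%. The arms shared 716 to 1623 genes opposite. The tissue calls shared 1149 to 2380 opposite and 1143 to 1805 alike with the RNA arm, and 722 to 1062 and 814 to 1493 with PhSpMo. Adjusted p ranged from 0.674 to 0.939 for innate immune response with the RNA, and with PhSpMo from 0.662 to 0.986 for FGF ligands and receptors and from 0.419 to 0.977 for cell cycle. Innate immune response lost its call with PhSpMo without control marginal zone replicate 1 or 2 (0.0608 and 0.179). Between the tissues, heat shock and unfolded protein stress did without the same samples (0.0506 and 0.0679), FGF ligands and receptors without control ectoderm replicate 1 or 2 (0.0692 and 0.0537), and germ plasm without the latter (0.0559). Low counts limit chrng.L, krt12.5.L, fucolectin.S, slc26a4l.L, otog.L, adgrf1.L and atp6v0d2.L, whose calls ended without 1 or more samples.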

Other observations

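The tests of the p53 genes' shared and mirrored changes, of the pnhd.S ratio, of the share of mesoderm cells and of scaling were chosen after the results were seen.

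The rule for the largest changes set its floor on average CPM over all groups, so genes low in either tissue can enter through the other. Thus zg16.S, at 3.88 CPM with PhSpMo and 0.213 in its controls, can enter through its 9.34 CPM in Flag-Pinhead ectoderm. Likewise sebox.L, at 2.14 CPM there, can enter through its 18.2 CPM in control marginal zone. The counts below therefore do not measure how far the arms share changes. Most of the named genes that rose most with PhSpMo also rose with Flag-Pinhead RNA. Of the 10 with the largest rise, 9 passed in the RNA arm in the same direction, with a ratio of counts of 174 (counting interval 47.8 to 1450) there for zg16.S and log2 fold changes of 6.37 for col17a1.L, 6.3 for chrng.L, 4.64 for slc26a9.S, 4.51 for nppb.S, 4.44 for sctr.L, 4.07 for nt5c3a.L, 3.3 for c3ar1.L and 2.99 for tnfrsf6b.L. The exception was trnal-aag, at -1.66 (SE 1.01, adjusted p = 0.251). The genes with the largest rise in the RNA arm mostly went the other way: of the 9 besides pnhd.L, whose RNA was injected, 7 fell with PhSpMo, among them t.S, wnt8a.S, sebox.L and hes5.9.L, bix4.L stood at -0.08 (SE 0.10, adjusted p = 0.647), and zg16.S rose. Of the 10 with the largest fall in the RNA arm, 5 also fell with PhSpMo (nedd9.L, xepsin.L, rgs2.L, rgcc.L and s1pr5.L), 1 rose (foxi4.2.S) and the others did not pass. Of the 10 with the largest fall with PhSpMo, socs3.L and krt.S fell with the RNA too, and hoxd1.S, otog.L and slc26a4l.L rose.

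Genes of the p53 response list rose in PhSpMo explants, and 10 of the 12 that rose also rose with Flag-Pinhead RNA (15 of 25 members rose there; one-sided Fisher's exact test within the list, p = 0.0287). The 2 others were tp53inp1.S and ddb2.L. The 10 that rose in both arms did not change as mirrors of added Pinhead. Counting falls with the RNA cannot decide more, since of all 25 members 1, ddb2.L, fell there. The 3 members that fell with PhSpMo, btg2.S, plk3.L and sesn2.L, all rose with the RNA, which is a mirrored change. The scaling of the libraries moves every gene alike and is argued against. The list had already passed camera's test, which likewise sets members against all other genes, so the next value adds little. The 25 members differed from all other tested genes by 0.42 in log2 fold change (Hodges-Lehmann estimate, 95% interval 0.11 to 0.93). Genes are not independent replicates, so the interval may be too narrow. A response to injection that both arms share may account for the shared rises, with the controls being untreated. A p53 response to each treatment in its own right stays open, since no group received a control injection.

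Lists of mesoderm, endoderm, epidermis and neural plate fell in PhSpMo explants, those of epidermis and neural plate with adjusted p = 0.0605 and 0.0711 with an estimated correlation. The scaling of the libraries is argued against. Of 124 distinct members of these lists 72 fell, and the 124 differed from all other tested genes by -0.78 in log2 fold change (Hodges-Lehmann estimate, 95% interval -0.89 to -0.67). Genes are not independent replicates, so the interval may be too narrow. The lists had already passed camera's test, which likewise sets members against all other genes. A lower share of mesoderm cells would raise markers of other layers that are not themselves marginal zone genes. Of 98 distinct endoderm, epidermis and neural plate genes 57 fell and 1, gmnn.L, rose. In controls all 20 endoderm and 27 of 48 neural plate members were higher in marginal zone than in ectoderm, so this count cannot decide. Of the 30 epidermis members 19 were lower in control marginal zone. With PhSpMo 19 of the 30 fell and none rose, so no gain of epidermis genes was seen. A lower share of mesoderm cells stays open. A delay in development, a response to injection and the loss of Pinhead itself stay open as well and were not tested. Of 30 epidermis members 17 also fell with Flag-Pinhead RNA, where the list's camera adjusted p was 0.0767 with an estimated correlation.

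Counts of pnhd.S rose in Flag-Pinhead explants, where reads of the injected RNA assigned to pnhd.S are a candidate explanation. The ratio of pnhd.S to pnhd.L counts in Flag-Pinhead replicate 2 was 0.394 times that in replicate 1 (exact 95% counting interval 0.32 to 0.485), while misassigned reads would keep it at 1 in both. Such reads could not then make up the whole of these counts, and the embryo's own pnhd.S may have risen with added Pinhead; part of the counts can still come from the injected RNA.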
